A study of Mus musculus with 16 samples.

How the data were processed

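Liver RNA of male C57BL/6 mice was measured on 16 Illumina bead arrays, 4 for each of 4 groups given by genotype and treatment. Per the labels' protocols, each mouse was given T3 at 1 mg per kg, or DMSO alone, by mouth once a day, and dosing lasted 3 days. RNA was isolated with Trizol, purified on columns with a DNase step, and turned into biotin-labelled cRNA. Groups and replicate numbers come from the sample titles. The labels do not say whether each array is a separate animal, so p-values measure the spread between these samples.

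The deposited intensity values are mean bead intensities per probe on a linear scale, not normalised between arrays, per the file headers. The deposited detection p-values, also per the file headers, state for each probe and array how often negative controls were as bright. GenomeStudio and lumi are named in the submitters' processing notes, with versions not given in the sources used here. A second table holds values that the authors normalised, here read as log2, and each of its 16 columns has a median of 6.38 and the same distribution. Each column ranked the probes exactly as the intensities of the array of the same title did (lowest rank correlation 1). Its exact transformation and any centring stay unknown, and it served only as an alternative. The intensity table also held 32 further per-sample columns, which were not used. No array positions, slides or dates were in the sources used here.

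Intensities were corrected and normalised with limma 3.58.1 in R 4.3.3: normexp background correction with negative controls inferred from the detection p-values, an offset of 16, quantile normalisation and log2. A probe was above background on an array at a detection p under 0.01, and was tested if that held on at least 4 of 16 arrays. This kept 14279 of 45281 probes. The annotation table paired 34885 probes with 1 gene symbol and 18 with several, and 10378 probes were not listed in it. Probes with several symbols were left unnamed. Symbols were updated by Entrez number for 34807 probes, and 12226 tested probes stood for 8556 genes. Each gene was represented by its brightest tested probe, and 2724 genes had more than 1 tested probe. Gene order on chromosome 7 was taken from assembly GRCm38.p6, and no coordinates are given because the build behind the probes is not given in the sources used here.

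All 16 arrays entered 1 linear model with 4 groups (lmFit and eBayes of limma; 12 residual and 2.91 prior degrees of freedom). The contrasts were T3 against vehicle in each genotype, the difference of these responses, and arrays labelled knockout against wild type under vehicle and under T3. A probe was called at an adjusted p under 0.05 (Benjamini-Hochberg over the tested probes of a contrast, 2-sided). Where no tested probe of a gene was above background on any array of the dimmer group, its fold is given as a lower bound (at least): the brighter group's mean log2 value minus the mean, over the dimmer group's arrays, of the higher of the probe's own value and the array's floor, which is the lowest value of any probe above background there. List medians that change with such members at their bound are also given so, with 0 for a bound under 1-fold and without members below background in both groups. For the difference of responses they are given over the members that need no bound. A bound corrects for background only and carries no sampling error, so it is not a confidence limit. A gene above background on only some arrays of the dimmer group keeps its fitted fold, whose size then rests in part on values below background. For 40 gene lists of 635 entries, 34 had at least 3 tested members and were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast and again with an estimated correlation. The other 6 lists had fewer tested members and were not tested as lists. Single values were compared between groups by exact permutation tests, and correlations across arrays by 100000 permutations. The relation of the T3 and genotype effects, which share the wild type vehicle arrays, was set beside 100 simulations without any effect. Counts of called probes were set beside those of other splits of the same arrays.

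The genes named are, for each contrast, the 10 highest and 10 lowest fold changes among genes that were called and whose 4 arrays of a group lay beyond all 4 of the other, and for the difference of responses those that were called. For each list discussed, up to 2 called members with the highest and 2 with the lowest fold changes may be named, or the 2 with the smallest p where none was called. Fgf21 and genes near it may be named in every knockout contrast. Genes named outside this rule are said to be so where they appear. The groups, the design, the lists, the rule for named genes and most alternatives were chosen before the data were examined.

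The procedure was tested on simulated data with independent arrays, in which 200 of 14279 probes were changed. It recovered 19.4%, 47.8% and 83.3% of probes changed 1.5-fold, 2-fold and 4-fold for T3 in wild type, and 16.4%, 50.7% and 87.9% for T3 in the arrays labelled knockout. For the genotype difference it recovered 16.4%, 46.3% and 90.9% under vehicle and 22.4%, 44.8% and 90.9% under T3, and for the difference of responses 5.97%, 26.9% and 66.7%. False calls made up 4.76%, 8.85%, 7.27%, 4.55% and 9.59% of the calls in the same order. With a component of variation between arrays added that the probes share, sized from the real residuals, it recovered 0%, 22.4% and 62.1% for the difference of responses, with 1.75% false calls. In the other contrasts it then recovered 16.4% to 19.4% at 1.5-fold, 52.2% to 59.7% at 2-fold and 89.4% to 93.9% at 4-fold, with 0% false calls. Both simulations used the same random draw for every contrast, so their shares of false calls rest on 1 draw. They held at most 1 component shared between probes, whereas another split of the real vehicle arrays gave 4944 called probes. The shares of false calls may therefore be higher in the real data. In the real data the median 95% confidence interval reached 0.49 log2 units to either side between 2 groups and 0.69 for the difference of responses.

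Alternatives were the authors' deposited values, no background correction, an offset of 50, median scaling, other filters on dim probes, a fold change minimum of 1.5, robust eBayes with an intensity trend, array weights, only the 8 arrays compared, the replicate number as a block, the mean of all probes of a gene, and each array left out in turn. Array brightness (log2 of the 95th percentile signal) or the ribosomal protein mean as a covariate, and the omission of the dimmest and the 2 brightest arrays, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.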

Results

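Liver RNA was measured on 16 Illumina mouse bead arrays of 45281 probes each. The arrays formed 4 groups of 4: wild type mice given vehicle, wild type mice given T3 (the active thyroid hormone), mice labelled as lacking Fgf21 given vehicle, and mice labelled as lacking Fgf21 given T3. The T3 dose was 1 mg per kg of body weight a day for 3 days, and the vehicle was DMSO. The median signal of an array ranged from 61.5 to 134.0, and between 11051 and 14111 probes (24.4% to 31.2%) were above background on an array. On average 12230 probes were above background in wild type vehicle, 12783 in wild type T3, 13694 in knockout vehicle and 12952.5 in knockout T3. The number of arrays, 4 per group, limits the precision of every comparison.

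Fgf21, which encodes a hormone made in the liver, is the gene targeted in the knockout and is measured by 1 probe. Its normalised log2 signal averaged 8.05 ± 0.88 (SD, n = 4) in wild type vehicle and 10.80 ± 1.27 (n = 4) in wild type T3. In the arrays labelled knockout it averaged 7.96 ± 0.43 (n = 4) under vehicle and 9.19 ± 1.86 (n = 4) under T3. The wild type vehicle arrays gave 9.11, 7.17, 8.41 and 7.50, and the wild type T3 arrays 10.01, 12.28, 11.39 and 9.50. The arrays labelled knockout gave 7.42, 8.43, 7.85 and 8.15 under vehicle and 9.24, 7.74, 7.99 and 11.80 under T3. The probe was above background on 3 of 4 wild type vehicle arrays and on all 12 others, so its signal did not separate the genotypes. Between the genotypes it differed by a log2 fold change of -0.09 (SE 0.78, adjusted p = 0.940) under vehicle and of -1.60 (SE 0.78, adjusted p = 0.815) under T3. Whether the probe lies inside the deleted part of the gene is not given in the sources used here, and a probe outside it would not check the labels. The groups are therefore called arrays labelled knockout, and single arrays are named by their label and replicate, such as knockout vehicle replicate 1.

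**Figure D1:**
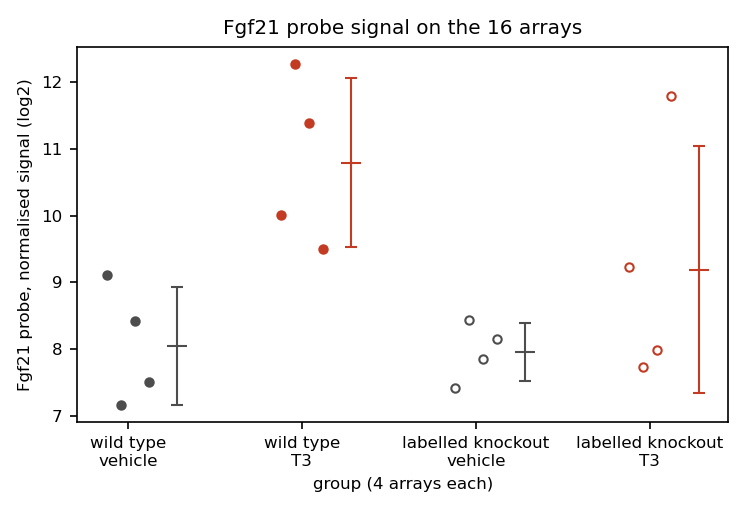
Normalised log2 signal of the Fgf21 probe (vertical axis) on each of the 16 arrays by group (horizontal axis). Points are arrays and bars are the mean ± SD of 4 arrays. Among the arrays labelled knockout, replicate 4 under T3 reached 11.80 and the 3 other T3 arrays lay between 7.74 and 9.24.

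In wild type liver Fgf21 rose 6.72-fold with T3 (log2 fold change 2.75, SE 0.78, adjusted p = 0.0367). This call was lost without wild type vehicle replicate 2 (adjusted p = 0.0999), replicate 3 (0.0668) or replicate 4 (0.0825), and without wild type T3 replicate 2 (0.121) or replicate 3 (0.0956). It was also lost with no filter on dim probes (adjusted p = 0.111) and with array brightness in the model (0.0514), and the log2 fold change stayed between 2.25 and 3.18 when single arrays were left out. In the arrays labelled knockout the T3 difference of Fgf21 was 1.23 (adjusted p = 0.408), and the T3 response differed between genotypes by -1.52 (SE 1.11, adjusted p = 0.563).

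Ribosomal protein genes, which encode parts of the ribosome, followed the main axis of variation between arrays. The first principal component held 41.2% of the variance and the second 26.3%. Across the 16 arrays the first component correlated with the mean of 12 ribosomal protein genes (r = 0.949, rho = 0.921, permutation p = 1e-05, the smallest 100000 permutations can give, adjusted 3e-05 over 3 relations). The correlation was 0.940 without the 2 arrays farthest from the median and 0.933 within groups. It also followed the log2 of the 95th percentile signal (r = 0.822, permutation p = 4e-05, adjusted 6e-05; rho = 0.744, permutation p = 0.00132; 0.765 without 2 arrays) and the number of probes above background (r = 0.799, permutation p = 0.00015, adjusted 0.00015; rho = 0.712, permutation p = 0.00278; 0.626 without 2 arrays). The ribosomal mean was 12.17 ± 0.19 (SD, n = 4) in wild type vehicle, 12.52 ± 0.20 in wild type T3, 12.50 ± 0.30 in knockout vehicle and 12.49 ± 0.11 in knockout T3. Wild type vehicle was also the dimmest group, with a mean 95th percentile signal of 2769 against 3335, 4631 and 3497 in the same order.

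The first comparison asks what T3 changed in wild type liver. T3 raised Rnase2a, a ribonuclease of the eosinophil-associated family, at least 24.4-fold (adjusted p = 0.000567), Crybb3, a lens crystallin gene, at least 19.2-fold (adjusted p = 2.51e-05), and Sspo, which encodes the secreted glycoprotein SCO-spondin, at least 14.6-fold (adjusted p = 7.83e-07). These bounds correct for background only and not for the spread between arrays. The log2 values of Rnase2a in wild type T3 had an SD of 2.21 (n = 4). Pfkfb4, a regulator of glycolysis, rose by a log2 fold change of 3.97 (SE 0.48, adjusted p = 0.000199), and the kinase gene Ttbk1 by 4.00 (SE 0.43, adjusted p = 7.68e-05; above background on 2 of 4 vehicle arrays). Serpina7, the gene of thyroxine-binding globulin, fell by 4.48 (SE 0.53, adjusted p = 0.000162; above background on 1 of 4 T3 arrays). The size of this fall rests mostly on T3 values below background. Abcc3, a transporter that exports bile salts and conjugates, fell by 3.71 (SE 0.25, adjusted p = 1.45e-06), and Vldlr, the receptor of very low density lipoprotein, fell by 3.37 (SE 0.57, adjusted p = 0.00193; above background on 1 of 4 T3 arrays) on all 3 of its probes. All values compare 4 T3 with 4 vehicle arrays.

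The other genes of largest change followed the same split. Nt5e, which encodes an ecto-nucleotidase, rose at least 7.95-fold, the potassium channel gene Kcnk1 at least 5.12-fold, Cep126 at least 5.01-fold, the carboxylesterase gene Ces4a at least 3.52-fold and the aldo-keto reductase gene Akr1c18 at least 3.25-fold. Etnppl, which encodes ethanolamine-phosphate phospho-lyase, was at least 8.73-fold lower, the transporter gene Abca8a at least 6.51-fold lower and Hectd2os at least 2.84-fold lower. Hsd17b6, a hydroxysteroid dehydrogenase gene, fell by 3.98 (SE 0.53), Hamp2, a hepcidin gene, fell by 3.64 (SE 0.56) and the desmoglein gene Dsg1c fell by 3.43 (SE 0.44). Hsd17b6 was above background on 1 and Dsg1c on 2 of the 4 T3 arrays. The brighter probe of Lpgat1 fell by 3.33 (SE 0.49), while its other tested probe was called higher, so the direction of this gene is not settled. The calls of all 20 of these genes held with each array left out in turn.

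With limma, 1509 of 14279 probes changed with T3 in wild type liver, 765 higher and 744 lower, which stood for 987 of 8556 genes. An unadjusted p under the threshold was reached by 3777 probes where 714 are expected by chance, and 821 of the called probes changed at least 2-fold. The count was 920 without wild type vehicle replicate 3 and 912 without wild type T3 replicate 2. It was 7351 with array weights, 2555 with the ribosomal mean in the model and 878 when a probe had to be above background on all 16 arrays.

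Genes known to be induced by thyroid hormone in liver rose as a group in wild type. Of 12 measured, 4 rose (6 adjusted over the list alone; median log2 fold change 1.02, or 0.72 with members not above background under vehicle at their bound; camera adjusted p = 0.00114; adjusted p = 0.287 with an estimated correlation). Dio1, a deiodinase and a classical target of the hormone, rose by 3.12 (SE 0.62, adjusted p = 0.00554). Hr, a corepressor of the thyroid hormone receptor, rose by 1.81 (SE 0.47, adjusted p = 0.0227; above background on 2 of 4 vehicle arrays), a call lost without wild type vehicle replicate 2 (0.069), 3 (0.0516) or 4 (0.0614) or wild type T3 replicate 2 (0.0761).

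Cholesterol synthesis and uptake genes rose, with 8 of 17 called (12 adjusted over the list alone; median 0.86, camera adjusted p = 8.9e-07; adjusted p = 0.287 with an estimated correlation). Mvd, which encodes mevalonate diphosphate decarboxylase, rose by 1.49 (SE 0.31, adjusted p = 0.00765). Sqle, which encodes squalene epoxidase, rose by 2.33 (SE 0.58, adjusted p = 0.0201), a call lost without wild type vehicle replicate 1 (0.0565) or 3 (0.0605) or wild type T3 replicate 2 (0.0661). Of 11 tricarboxylic acid cycle genes 2 rose (5 adjusted over the list alone; median 0.20, camera adjusted p = 0.0301; adjusted p = 0.446 with an estimated correlation). Idh3a, a subunit of isocitrate dehydrogenase, rose by 1.28 (SE 0.18, adjusted p = 0.000559). With median scaling the median of this list was -0.05, and its call was lost without wild type vehicle replicate 1 (0.0923) or wild type T3 replicate 2 (0.075) or 3 (0.0524).

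Genes of xenobiotic metabolism fell, with 7 of 16 called lower (8 adjusted over the list alone; median -0.96, camera adjusted p = 0.000412; adjusted p = 0.253 with an estimated correlation). The cytochrome P450 gene Cyp2c29 fell by 2.75 (SE 0.35, adjusted p = 0.000263). Fatty acid synthesis genes did not pass as a group (camera adjusted p = 0.760), and their median of -0.09 and mean of 0.11 differ in sign. Within that list 1 of 18 genes was called higher and 1 lower (2 and 1 adjusted over the list alone). Pklr, the liver pyruvate kinase gene, fell by 1.74 (SE 0.33, adjusted p = 0.00398; above background on 1 of 4 T3 arrays). Pnpla3 rose by 3.00 (SE 0.88, adjusted p = 0.0407; above background on 3 of 4 vehicle arrays), a call lost without any 1 of 9 arrays (adjusted p up to 0.129, without wild type T3 replicate 2). Bile acid genes did not pass either (median 0.00, camera adjusted p = 0.722), with 1 of 16 called higher and 1 lower, also adjusted over the list alone. Cyp7b1, an oxysterol hydroxylase gene, rose by 1.40 (SE 0.31, adjusted p = 0.0112). Nr1h4, the bile acid receptor gene, fell by 0.46 (SE 0.13, adjusted p = 0.0344), a call lost without any 1 of 6 arrays (adjusted p up to 0.111, without wild type T3 replicate 2).

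Markers of Kupffer cells and other macrophages rose in wild type liver under T3. All 12 measured markers were called higher (12 adjusted over the list alone; median 2.19, or 2.06 with 4 members at their bound; camera adjusted p = 2.15e-11; adjusted p = 0.287 with an estimated correlation). Folr2, a folate receptor of resident macrophages, rose at least 3.12-fold and C1qc, a complement component gene, at least 4.50-fold. The mean of these markers was 8.09 ± 0.42 (SD, n = 4) in wild type vehicle, 10.36 ± 0.67 in wild type T3, 9.91 ± 0.78 in knockout vehicle and 10.96 ± 0.21 in knockout T3. Endothelial markers (median 0.08, or 0.07 with bounds; camera adjusted p = 0.557) and stellate cell and fibroblast markers (median 0.43, or 0.15; camera adjusted p = 0.0956) did not pass.

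Interferon response genes also rose, with 7 of 12 called (10 adjusted over the list alone, median 1.00, or 0.89 with bounds, camera adjusted p = 3.13e-05, adjusted p = 0.434 with an estimated correlation). Gbp3, an interferon-induced GTPase gene, rose by 2.20 (SE 0.43, adjusted p = 0.00487). Of 16 cell cycle genes 8 rose (13 adjusted over the list alone; median 1.41, or 0.69 with 9 members at their bound; camera adjusted p = 7.21e-07; adjusted p = 0.434 with an estimated correlation). Mcm5, a part of the replicative helicase, rose at least 3.27-fold (adjusted p = 0.00695). Of 19 acute phase genes 3 rose (6 adjusted over the list alone; median 0.49, camera adjusted p = 0.00938; adjusted p = 0.446 with an estimated correlation). The macrophage marker mean was higher by 2.27 in the same arrays (exact permutation p = 0.0286, the smallest that 4 against 4 allows).

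**Figure D2:**
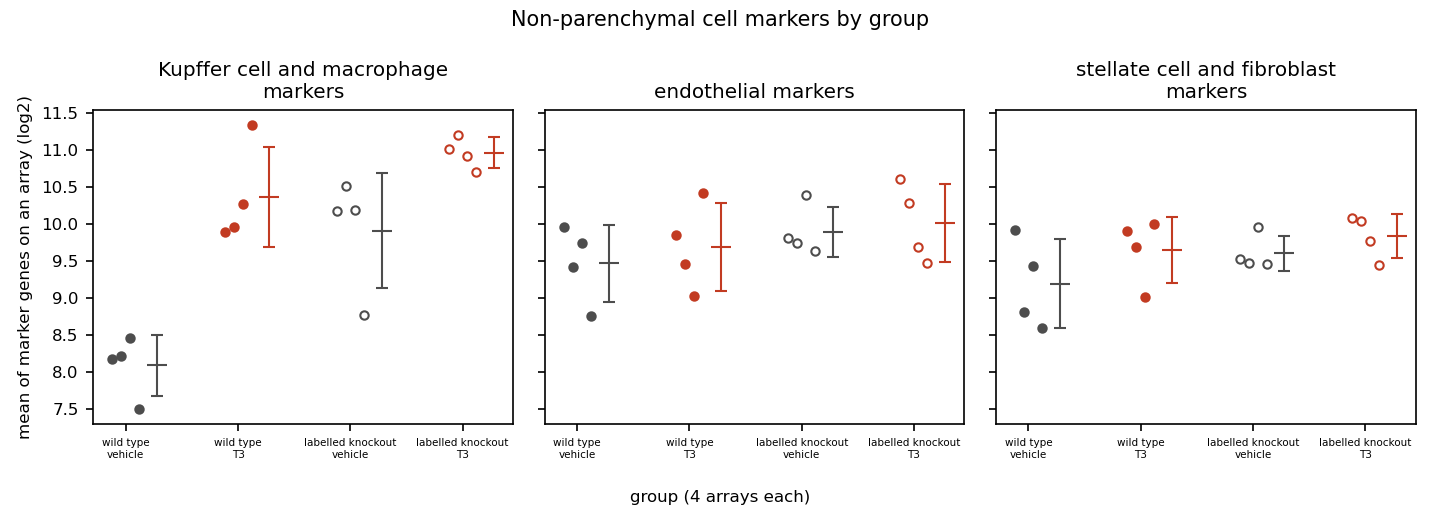
Mean log2 signal of the markers of 3 non-parenchymal cell types (vertical axis) on each array by group (horizontal axis). Points are arrays and bars are the mean ± SD of 4 arrays. The macrophage mean was 8.09 in wild type vehicle and between 9.91 and 10.96 in the 3 other groups, while the endothelial means lay between 9.47 and 10.01.

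The second comparison asks what T3 changed in the arrays labelled knockout. Rnase2a rose by a log2 fold change of 7.13 (SE 0.86, adjusted p = 0.000265; above background on 1 of 4 vehicle arrays) and Crybb3 by 4.32 (SE 0.46, adjusted p = 9.79e-05; 1 of 4). Both sizes rest mostly on vehicle values below background and cannot be set beside the lower bounds given for wild type. Sspo rose at least 13.1-fold (adjusted p = 2.1e-06), Cep126 at least 6.35-fold, Akr1c18 at least 3.75-fold and Ces4a at least 3.58-fold. Akr1c18 was above background on 3 of 4 T3 arrays. Ttbk1 rose by 3.92 (SE 0.43) and Pfkfb4 by 3.59 (SE 0.48, adjusted p = 0.000601). Serpina7 fell by 4.29 (SE 0.53, adjusted p = 0.000337; above background on 2 of 4 T3 arrays), Cyp4a12b, a fatty acid hydroxylase gene, fell by 4.77 (SE 0.97, adjusted p = 0.0101; 3 of 4), and Cyp2c23, an epoxygenase gene, and Abcc3 each fell by 3.33 (SE 0.26 and 0.25, adjusted p = 3.73e-06 for each). All values compare 4 T3 with 4 vehicle arrays.

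Etnppl was at least 9.39-fold lower, the oxysterol-binding protein gene Osbpl3 at least 5.50-fold lower, Abca8a at least 4.97-fold lower and the sulfotransferase gene Gal3st1 at least 4.38-fold lower. Gm4956 fell by 3.55 (SE 0.56; above background on 2 of 4 T3 arrays) and the glutathione transferase gene Gsta2 by 3.27 (SE 0.45; 1 of 4). Cux2, a transcription factor gene with female-biased liver expression, rose at least 6.52-fold (adjusted p = 0.0212), and Pnpla3, a lipase gene, rose by 3.74 (SE 0.88, adjusted p = 0.0215; above background on 3 of 4 vehicle arrays). The Cux2 call was lost without knockout vehicle replicate 1 (0.0739) or 4 (0.0511) or knockout T3 replicate 4 (0.0765). The Pnpla3 call was lost without knockout vehicle replicate 1 (0.0684) or 4 (0.0654) or knockout T3 replicate 2 (0.0566) or 4 (0.0604). The calls of the 18 other genes held with each array left out in turn.

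With limma, 796 of 14279 probes changed with T3 in the arrays labelled knockout, 419 higher and 377 lower, and 2939 had an unadjusted p under the threshold. These stood for 507 genes, and 451 of the probes changed at least 2-fold. The count was 359 without knockout vehicle replicate 1, 1241 without replicate 3, 479 without replicate 4, 479 without knockout T3 replicate 1 and 437 without knockout T3 replicate 4. It was 473 with median scaling (174 higher, 299 lower), 389 when only these 8 arrays were fitted, 4192 with array weights and 2706 with the ribosomal mean in the model.

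Interferon response genes rose in the arrays labelled knockout, with 6 of 12 called (9 adjusted over the list alone; median 0.96, camera adjusted p = 3.57e-06; adjusted p = 0.259 with an estimated correlation). Gbp3 rose by 2.05 (SE 0.43, adjusted p = 0.011) and Isg15, an interferon-induced ubiquitin-like modifier, by 1.49 (SE 0.30, adjusted p = 0.00981). Macrophage markers rose with 2 of 12 called (4 adjusted over the list alone; median 1.01, camera adjusted p = 0.000198; adjusted p = 0.545 with an estimated correlation), and Folr2 rose by 1.70 (SE 0.36, adjusted p = 0.0119; above background on 3 of 4 vehicle arrays). Of 17 cholesterol genes 4 rose (9 adjusted over the list alone; median 0.55, camera adjusted p = 0.00111; adjusted p = 0.505 with an estimated correlation), and the list's call was lost without knockout vehicle replicate 3 (0.0736). Mvd rose by 1.77 (SE 0.31, adjusted p = 0.00394). Of 16 cell cycle genes 1 was called, with 7 adjusted over the list alone (median 0.93, or 0.80 with bounds; camera adjusted p = 0.00231; adjusted p = 0.602 with an estimated correlation).

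Genes of xenobiotic metabolism fell with 7 of 16 called lower (7 adjusted over the list alone; median -0.83, or -0.71 with bounds; camera adjusted p = 7.05e-06; adjusted p = 0.0542 with an estimated correlation). Urea cycle and amino acid catabolism genes fell with 4 of 16 called (6 adjusted over the list alone; median -0.39, camera adjusted p = 0.000156; adjusted p = 0.208 with an estimated correlation), among them Oat, the ornithine aminotransferase gene, by 1.64 (SE 0.20, adjusted p = 0.000236). Gluconeogenesis genes fell with 1 of 8 called (3 adjusted over the list alone; median -0.40, camera adjusted p = 0.00111; adjusted p = 0.159 with an estimated correlation). Fbp1, the gene of fructose bisphosphatase, fell by 1.47 (SE 0.33, adjusted p = 0.0162), a call lost without knockout vehicle replicate 1 (0.0671) or knockout T3 replicate 4 (0.0516).

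PPAR alpha targets fell with 1 of 12 called (3 adjusted over the list alone; median -0.34, camera adjusted p = 0.0113; adjusted p = 0.465 with an estimated correlation). Acot1, an acyl-CoA thioesterase gene, fell by 2.23 (SE 0.43, adjusted p = 0.00757). Fatty acid oxidation and ketogenesis genes fell with 1 of 16 called, also 1 adjusted over the list alone (median -0.17, camera adjusted p = 0.0242; adjusted p = 0.545 with an estimated correlation). Acadm, the medium-chain acyl-CoA dehydrogenase gene, fell by 1.12 (SE 0.23, adjusted p = 0.011). Of 17 lipoprotein genes none was called by limma, and 1 higher and 1 lower passed adjusted over the list alone (median -0.21, camera adjusted p = 0.0411; adjusted p = 0.208 with an estimated correlation). The PPAR alpha call was lost without knockout vehicle replicate 2 (0.0855) or knockout T3 replicate 3 (0.131), and the fatty acid oxidation call without knockout vehicle replicate 2 (0.0773) or 4 (0.0547) or knockout T3 replicate 3 (0.136). The lipoprotein call was lost without wild type T3 replicate 2 (0.0525) or 4 (0.0531), knockout vehicle replicate 2 (0.167), or knockout T3 replicate 1 (0.0526), 3 (0.0908) or 4 (0.0608).

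The list of thyroid hormone induced genes did not pass in the arrays labelled knockout (median 0.21, camera adjusted p = 0.107), with 3 of 12 members called (4 adjusted over the list alone). Bcl3, a regulator of NF-kappa-B, rose by 2.10 (SE 0.33, adjusted p = 0.002; above background on 3 of 4 vehicle arrays). Hr rose by 2.02 (SE 0.47, adjusted p = 0.0201), a call lost without knockout vehicle replicate 1 (0.0815) or 4 (0.0538) or knockout T3 replicate 1 (0.0651) or 2 (0.0618). The difference between genotypes in this list was not called (median -0.36, or -0.25 over the 11 measured members; camera adjusted p = 0.108).

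**Figure D3:**
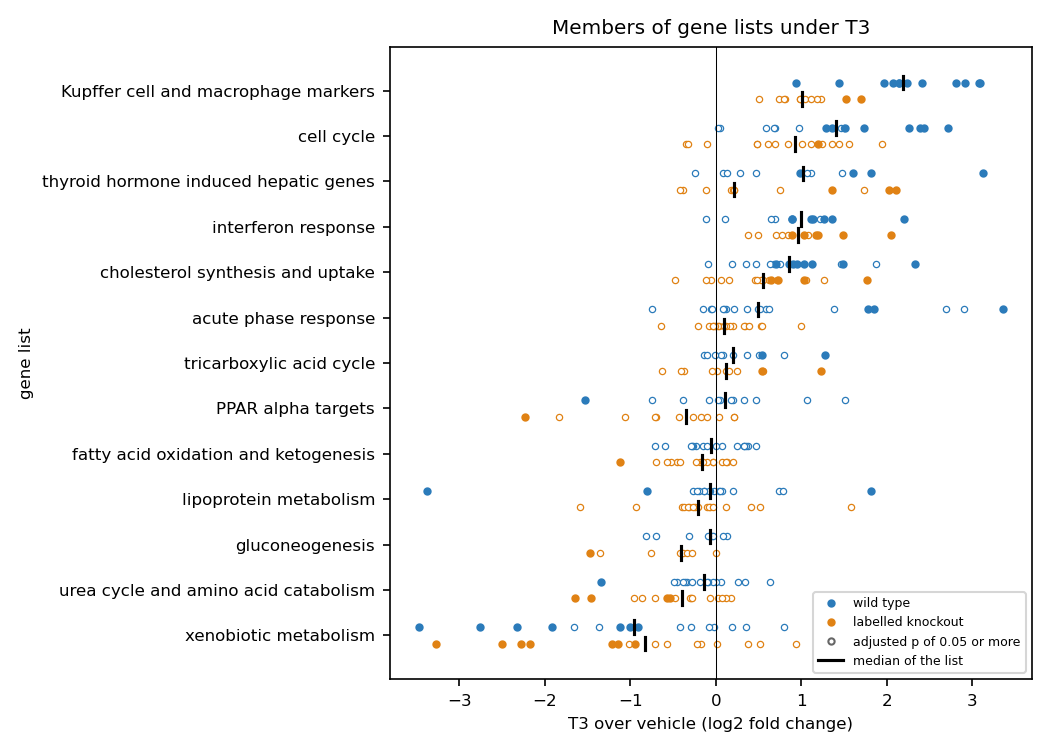
Log2 fold change of T3 over vehicle (horizontal axis) for the measured members of the 13 gene lists called in wild type or in the arrays labelled knockout (vertical axis). Points are genes, filled where the gene's adjusted p passed, and vertical strokes are list medians. The macrophage median was 2.19 in wild type and 1.01 in the arrays labelled knockout, and the xenobiotic medians were -0.96 and -0.83.

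The third comparison asks whether the T3 response differs between genotypes. No gene was called: limma found 0 probes (smallest adjusted p = 0.263), and 1146 probes had an unadjusted p under the threshold where 714 are expected by chance. Of 100 groupings of the arrays by genotype within each treatment, the real one counted among them, 18 gave at least 1146 such probes. Chance is therefore not excluded for that number. The 5 genes with the smallest p were Gprc5b (adjusted p = 0.263), Mppe1 (adjusted p = 0.410), Rrm2, Magi3 and Synm, the last 3 with an adjusted p of 0.554. They are named because no gene passed. Gprc5b was above background in knockout vehicle only, Mppe1 and Rrm2 on 0 of 4 wild type vehicle arrays and Synm on 0 of 4 wild type T3 arrays, so no size of the difference is given for these. Magi3 differed by 1.01 (SE 0.22) and was above background on 1 of 4 arrays in each knockout group. The median 95% confidence interval of such a difference reached 0.69 to either side. The count was 3 without knockout vehicle replicate 2 and 1 without replicate 4, and 6841 with array weights.

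Of the probes called for T3, 471 were called in both genotypes, and all 471 had the same sign. If the lists were independent, 22.4 probes would be higher in both, against 251 found, and 19.6 lower, against 220 found. Of the 1038 probes called in wild type alone, 93.6% had the same sign in the arrays labelled knockout, and of the 325 called in the latter alone 95.7% had the same sign in wild type. Across all probes, which are not independent replicates, the fold changes correlated at r = 0.564 with an orthogonal slope of 0.756. The median ratio of the knockout fold change to the wild type one was 0.603 among probes called in wild type, and the median ratio of wild type to knockout was 0.834 among probes called in the arrays labelled knockout. Each ratio was taken among probes called for its denominator, a choice that lowers it even where the responses are equal. Neither ratio therefore measures a weaker response. The correlation was 0.434 without wild type T3 replicate 4, 0.689 without knockout vehicle replicate 1, 0.687 without replicate 2, 0.390 without replicate 3 and 0.443 without replicate 4.

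**Figure D4:**
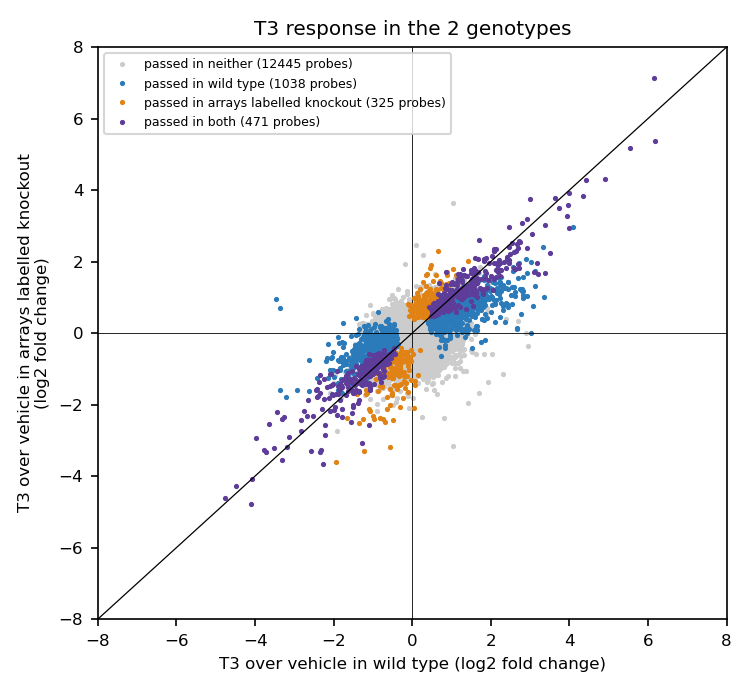
Log2 fold change of T3 over vehicle in wild type (horizontal axis) and in the arrays labelled knockout (vertical axis) for the 14279 tested probes, with the line of equal change. Colours mark the 471 probes called in both genotypes, the 1038 called in wild type alone and the 325 called in the arrays labelled knockout alone.

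Several gene lists had a T3 response of lower signed value in the arrays labelled knockout than in wild type, with 0 members called by limma and, except where given, 0 adjusted over the list alone. Macrophage markers differed by a median of -1.15 (camera adjusted p = 1.04e-06; adjusted p = 0.493 with an estimated correlation; 1 of 12 lower adjusted over the list alone), also over the 8 members measured in the groups compared. The smallest p among them belonged to C1qc (adjusted p = 0.554), which was above background on 0 of 4 wild type vehicle arrays. The marker means were 8.09 and 9.91 under vehicle and 10.36 and 10.96 under T3 in wild type and in the arrays labelled knockout, so the vehicle groups differed more than the T3 groups. On probes called for T3 in both genotypes, knockout vehicle replicate 2 lay 0.485 of the way from vehicle to T3. PPAR alpha targets differed by -0.58 (-0.46 over the 10 measured members; camera adjusted p = 0.00637; adjusted p = 0.493 with an estimated correlation), with Ehhadh, a peroxisomal enzyme gene, at -1.17 (SE 0.49, adjusted p = 0.554). The macrophage and PPAR alpha calls held with each array left out. Acute phase genes differed by -0.29 (camera adjusted p = 0.00637; adjusted p = 0.493 with an estimated correlation), a call lost without knockout vehicle replicate 3 (0.0706). Cell cycle genes differed by -0.54 (-0.15 over the 7 measured members; camera adjusted p = 0.00682; adjusted p = 0.512 with an estimated correlation; 1 of 16 lower adjusted over the list alone), a call lost without wild type T3 replicate 1 (0.0794) or 4 (0.139), knockout vehicle replicate 3 (0.0594) or knockout T3 replicate 4 (0.104); with array weights its median was 0.23.

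Some hepatocyte lists also differed in their T3 response, while pericentral markers did not pass (median 0.12, camera adjusted p = 0.710). Periportal markers differed by a median of -0.35 (camera adjusted p = 0.0221; adjusted p = 0.493 with an estimated correlation), urea cycle and amino acid catabolism genes by -0.25 (0.0407; adjusted p = 0.512 with an estimated correlation) and gluconeogenesis genes by -0.50 (0.0456; adjusted p = 0.493 with an estimated correlation). With median scaling the urea cycle difference turned to 0.31. The periportal call was lost without wild type T3 replicate 1 (0.0661), 3 (0.0563) or 4 (0.0702), knockout vehicle replicate 1 (0.0603) or 3 (0.0594), or knockout T3 replicate 1 (0.116). The urea cycle call was lost without any 1 of 10 arrays (adjusted p up to 0.104, without knockout T3 replicate 4) and the gluconeogenesis call without any 1 of 9 (up to 0.156, without wild type vehicle replicate 4).

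The next comparison sets arrays labelled knockout against wild type under vehicle. Saa4, which encodes a constitutive serum amyloid A protein, was lower by a log2 fold change of -7.60 (SE 0.43, adjusted p = 6.26e-08; above background on 1 of 4 arrays labelled knockout). The size of this difference rests mostly on values below background. Psmd8, a proteasome subunit gene, was lower by -3.08 (SE 0.11, adjusted p = 4.62e-10), Ttc23 at least 6.27-fold lower (adjusted p = 2.48e-07), and Hps5, a gene of lysosome-related organelle formation, at least 2.79-fold lower (adjusted p = 1.42e-06). Synm, which encodes the intermediate filament protein synemin, was higher by 2.86 (SE 0.24, adjusted p = 4.62e-06; above background on 1 of 4 wild type arrays). Saa4, Psmd8, Ttc23, Hps5 and Synm all lie on chromosome 7, as Fgf21 does. Each comparison is of 4 against 4 arrays, and the calls of these 5 genes held with each array left out.

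C1qc was at least 4.19-fold higher (adjusted p = 0.00696), Ly86, a partner of a Toll-like receptor homologue, at least 2.62-fold higher and Ms4a6d at least 1.83-fold higher, with Ms4a6d above background on 3 of 4 arrays labelled knockout. Emp1, an epithelial membrane protein gene, was higher by 2.37 (SE 0.33, adjusted p = 0.00222; above background on 1 of 4 wild type arrays). Lgals4, a galectin gene of chromosome 7, was lower by -2.42 (SE 0.44, adjusted p = 0.0131) on all 3 of its probes. These calls held with each array left out, and those of the following genes did not. C1qb (2.61), a complement gene, lost its call without wild type vehicle replicate 4 (0.0515) or knockout vehicle replicate 1 (0.0652) or 2 (0.0653), and Lyz2 (2.35), the lysozyme gene of myeloid cells, without wild type vehicle replicate 4 (0.0622) or knockout vehicle replicate 1 (0.0692) or 2 (0.0749). Vsig4 (2.60), a complement receptor gene of Kupffer cells, lost it without wild type vehicle replicate 1 (0.0508), 2 (0.0545) or 4 (0.0633) or knockout vehicle replicate 1 (0.0785) or 2 (0.0749). On the wild type arrays C1qb was above background on 3 of 4 and Lyz2 on 2 of 4. Of the 2 tested probes of Lyz2 1 was called, and both had the same sign.

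Ear3, at least 1.85-fold higher, lost its call without wild type vehicle replicate 2 (adjusted p = 0.0513) or 4 (0.0544) or knockout vehicle replicate 1 (0.0734) or 2 (0.0553). Osbpl3, higher by 2.36, lost it without wild type vehicle replicate 2 (0.0642) or 4 (0.0632) or knockout vehicle replicate 1 (0.069) or 2 (0.0508). Syne4, at least 3.25-fold lower, lost it without wild type vehicle replicate 2 (0.0816) or 4 (0.0656) or knockout vehicle replicate 1 (0.0875) or 2 (0.0969), and Ranbp3l (-1.84) without wild type vehicle replicate 2 (0.0752) or 4 (0.0656) or knockout vehicle replicate 1 (0.0668) or 2 (0.0791). Osbpl3 was above background on 2 of 4 wild type arrays, and Ranbp3l on 3 of 4 wild type arrays and 1 of 4 labelled knockout. The calls of the cytochrome P450 gene Cyp2b9 (at least 6.23-fold lower), Grtp1 (-1.82) and Josd2 (-1.69) were lost without any 1 of 10, 12 and 9 arrays, with adjusted p up to 0.139, 0.167 and 0.134, each without knockout vehicle replicate 2. Of the 2 tested probes of Grtp1 1 was called, and both had the same sign. In their brighter groups Cyp2b9 (wild type) and Ear3 (labelled knockout) were each above background on 3 of 4 arrays.

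With limma, 336 of 14279 probes were called between the genotypes under vehicle, 195 higher and 141 lower in the arrays labelled knockout, and 4433 had an unadjusted p under the threshold. They stood for 195 genes, 131 higher and 64 lower, and 229 of the probes differed at least 2-fold. The count was 113, 80, 134 and 93 without wild type vehicle replicates 1, 2, 3 and 4, 66, 72, 3978 and 1031 without knockout vehicle replicates 1, 2, 3 and 4, and 170, 201 and 179 without knockout T3 replicates 1, 2 and 3. It was 33 with array brightness in the model, 31 without the dimmest and the 2 brightest arrays, 191 with the ribosomal mean in the model, 20 when only these 8 arrays were fitted, 16 when a probe had to be above background on all 16 arrays and 8625 with array weights. Median scaling gave 361 higher and 74 lower, and no filter on dim probes 134 higher and 217 lower.

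Macrophage markers were higher in the arrays labelled knockout under vehicle, with 7 of 12 called (12 adjusted over the list alone; median 1.79, or 1.27 with 4 members at their bound; camera adjusted p = 1.7e-09; adjusted p = 0.736 with an estimated correlation). The macrophage mean was 9.91 ± 0.78 (SD, n = 4) against 8.09 ± 0.42 (n = 4) in wild type vehicle, with a difference of 1.82 (exact permutation p = 0.0286, the smallest that 4 against 4 allows). Array brightness differed between these groups too, with mean 95th percentile signals of 4631 and 2769, and with brightness in the model the markers' median was 1.58 (median SE 0.54 against 0.44) and 0 of 12 were called by limma. With the ribosomal mean in the model the median was 1.85 and 3 were called. Interferon response genes were higher with 3 of 12 called (5 adjusted over the list alone; median 0.69, or 0.57 with bounds; camera adjusted p = 0.00143; adjusted p = 0.736 with an estimated correlation), a call lost without knockout vehicle replicate 3 (0.0906). Ifit2, an interferon-induced gene, was at least 1.40-fold higher (adjusted p = 0.00737). Hmox1, the heme oxygenase gene, was at least 1.55-fold higher (adjusted p = 0.00211). Both gene calls held with each array left out.

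The T3 response in wild type and this genotype difference share the 4 wild type vehicle arrays. Across probes they correlated at r = 0.603 with a covariance of 0.223. With no effect, 100 simulations that shared the controls gave a mean r of 0.444 (95% of values from -0.365 to 0.917) and a mean covariance of 0.0476 (-0.0297 to 0.234). With the controls split into pairs, r ranged from 0.236 to 0.613 and the covariance from 0.113 to 0.221. There were 158 probes called in both, 152 of them with the same sign; because the controls are shared, no number expected by chance is given. The correlation was 0.662 without wild type vehicle replicate 4, 0.493 without wild type T3 replicate 2, 0.541 without wild type T3 replicate 3, 0.676 without wild type T3 replicate 4 and 0.530 without knockout vehicle replicate 2, and 0.398 with array brightness in the model.

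The last comparison sets arrays labelled knockout against wild type under T3. Saa4 was at least 112-fold lower (adjusted p = 6.17e-08), Psmd8 lower by -3.14 (SE 0.11, adjusted p = 3.56e-10), Ttc23 at least 3.87-fold lower, Ramac at least 3.32-fold lower, Hps5 at least 1.89-fold lower and Ctu1, a gene of tRNA thiolation, at least 1.72-fold lower. Atl3, which encodes an atlastin GTPase of the endoplasmic reticulum and lies on chromosome 19, was at least 8.58-fold lower (adjusted p = 0.00962) on all 4 of its probes. Under vehicle Atl3 was not called (log2 fold change -1.67, adjusted p = 0.101). There knockout vehicle replicate 2 read 6.35, near the knockout T3 mean of 6.61, and the other arrays of its group read 9.84 to 10.04. The wild type vehicle mean was 10.71, and Atl3 parted all 8 arrays labelled knockout from all 8 wild type arrays. The difference was therefore not confined to T3. Ppp1r14a, an inhibitor of myosin phosphatase, was higher by 2.29 (SE 0.36, adjusted p = 0.00776; above background on 1 of 4 wild type arrays), and Tead2, a transcription factor gene of the Hippo pathway, at least 3.58-fold higher (adjusted p = 0.00272). The calls of these 9 genes held with each array left out, and all of them except Atl3 lie on chromosome 7.

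The 11 other genes of largest difference lost their calls without some arrays. The stress gene Atf3 (at least 1.98-fold higher) lost its call without wild type T3 replicate 1 (adjusted p = 0.0947), 3 (0.0804) or 4 (0.0504) or knockout T3 replicate 1 (0.0661) or 4 (0.0713). The immediate early gene Fos (at least 1.60-fold higher) lost it without wild type T3 replicate 3 (0.0694) or 4 (0.0546) or knockout T3 replicate 1 (0.0638), 2 (0.0622) or 4 (0.0714). Synm (at least 1.89-fold higher) lost it without wild type T3 replicate 3 (0.0615) or knockout T3 replicate 1 (0.0548), and 0610005C13Rik (-1.82) without wild type T3 replicate 3 (0.0505) or knockout T3 replicate 4 (0.0501). Zfp30 (1.66; above background on 2 of 4 wild type arrays) lost it without wild type T3 replicate 1 (0.0537), 2 (0.0524) or 4 (0.0546) or knockout T3 replicate 3 (0.0535) or 4 (0.0914), and Snurf (1.17) without wild type T3 replicate 3 (0.0657) or any knockout T3 replicate (0.0536, 0.0535, 0.0533 and 0.0501). Ifit2 (1.44) lost it without wild type T3 replicates 1 (0.0937), 2 (0.0544) or 3 (0.0804) or knockout T3 replicates 1 (0.0674), 2 (0.0726) or 4 (0.0914), and Nosip (1.27) without wild type T3 replicates 1 (0.0697), 2 (0.053) or 3 (0.0706) or knockout T3 replicates 1 (0.0738), 3 (0.0533) or 4 (0.0587). Cd83 (at least 1.06-fold higher), Ttn (at least 1.42-fold lower) and Atf6 (at least 1.01-fold lower) lost it without any 1 of 12, 11 and 7 arrays, with adjusted p up to 0.152, 0.156 and 0.0963. Even in the brighter group, Cd83, Ttn and Fos were above background on 3 of 4 arrays and Atf6 on 2 of 4. Of the tested probes, 1 of 2 was called for Synm and for Ifit2, and 2 of 3 for Nosip and for Snurf, with the same sign within each gene.

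With limma, 67 of 14279 probes were called between the genotypes under T3, 19 higher and 48 lower, for 27 genes, and 909 had an unadjusted p under the threshold where 714 are expected by chance. Of the called probes 60 differed at least 2-fold. The count was 39 without wild type T3 replicate 1, 31 without wild type T3 replicate 3, and 40, 43 and 29 without knockout T3 replicates 1, 2 and 4. It was 13 when a probe had to be above background on all 16 arrays, 179 with the ribosomal mean in the model and 417 with array weights.

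Interferon response genes were higher in the arrays labelled knockout under T3, with 1 of 12 called (7 adjusted over the list alone; median 0.77, camera adjusted p = 1.61e-11; adjusted p = 0.258 with an estimated correlation). Macrophage markers had a median of 0.61 with none of 12 called by limma or adjusted over the list alone (camera adjusted p = 0.000959; adjusted p = 0.538 with an estimated correlation). Urea cycle and amino acid catabolism genes were lower by a median of -0.18 (camera adjusted p = 0.000815; adjusted p = 0.342 with an estimated correlation) and gluconeogenesis genes by -0.19 (camera adjusted p = 0.00316; adjusted p = 0.258 with an estimated correlation), with 0 members called by limma or adjusted over the list alone. These 4 list calls held with each array left out.

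Other list calls under T3 rested on single arrays. Cholesterol genes were lower (median -0.26, 0 of 17 called, 1 adjusted over the list alone; camera adjusted p = 0.00209; adjusted p = 0.435 with an estimated correlation), a call lost without wild type T3 replicate 2 (0.059) or knockout T3 replicate 1 (0.0713). Periportal markers were lower (median -0.23, 0 of 10 called, 0 adjusted over the list alone; camera adjusted p = 0.00265; adjusted p = 0.343 with an estimated correlation), a call lost without knockout T3 replicate 1 (0.227). Acute phase genes were lower (median -0.09, 1 of 19 called, 1 adjusted over the list alone; camera adjusted p = 0.00265; adjusted p = 0.343 with an estimated correlation), a call lost without wild type T3 replicate 3 (0.0791) or knockout T3 replicate 1 (0.0713); the called member was Saa4. FGF21 receptors and immediate early genes were higher (median 0.30, or 0.18 with bounds, 1 of 8 called, 1 adjusted over the list alone; camera adjusted p = 0.0213; adjusted p = 0.343 with an estimated correlation), a call lost without wild type T3 replicate 3 (0.088) or 4 (0.0916) or knockout T3 replicate 4 (0.0586); the called member was Fos. Neutrophil markers were higher (median 1.25, 0 of 3 called, 2 adjusted over the list alone; camera adjusted p = 0.026; adjusted p = 0.343 with an estimated correlation), a call lost without wild type T3 replicate 1 (0.144) or 3 (0.0633) or knockout T3 replicate 1 (0.0692) or 4 (0.0586).

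Genes near Fgf21 on chromosome 7 were compared in both knockout contrasts, each by its brightest probe. Under vehicle 2 of 14 were lower, Plekha4 by -1.58 (SE 0.26, adjusted p = 0.00861; above background on 1 of 4 arrays labelled knockout) and Tmem143 by -0.53 (SE 0.12, adjusted p = 0.0368); on the list alone 1 was higher and 2 lower (camera adjusted p = 0.269). The Plekha4 call held with each array left out and the Tmem143 call was lost without any 1 of 9 arrays (adjusted p up to 0.126, without knockout vehicle replicate 1). Under T3 none of these 14 was called by limma on its brightest probe, while adjusted over the list alone 2 were higher and 1 lower (camera adjusted p = 0.951). Car11 had a log2 fold change of 1.27 (adjusted p = 0.188; above background on 3 of 4 wild type arrays) and Dhdh of -0.61 (adjusted p = 0.405). A dimmer probe of Dhdh was called lower under both treatments, and dimmer probes of Emp3 and Grwd1 were called higher under vehicle. Chromosome 7 genes outside this fixed list were called under both treatments. Among them were 0610005C13Rik (adjusted p = 0.0311 under vehicle and 0.0103 under T3) and Tead2 (0.00825 and 0.00272). The list therefore does not stand for every gene around Fgf21. Of 8556 tested genes, 28 parted all 8 arrays labelled knockout from all 8 wild type arrays, which chance does for 0.0155% of genes, and 16 of the 28 were among the 658 tested genes of chromosome 7. In the gene order of assembly GRCm38.p6, the 12 chromosome 7 genes called under both treatments by their brightest probe ran from Psmd8, 100 tested genes before Fgf21, to Synm, 48 after it. Genes whose call under at least 1 treatment rests on a dimmer probe alone, such as Dhdh under both and Lgals4 under T3, are not counted there.

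**Figure D5:**
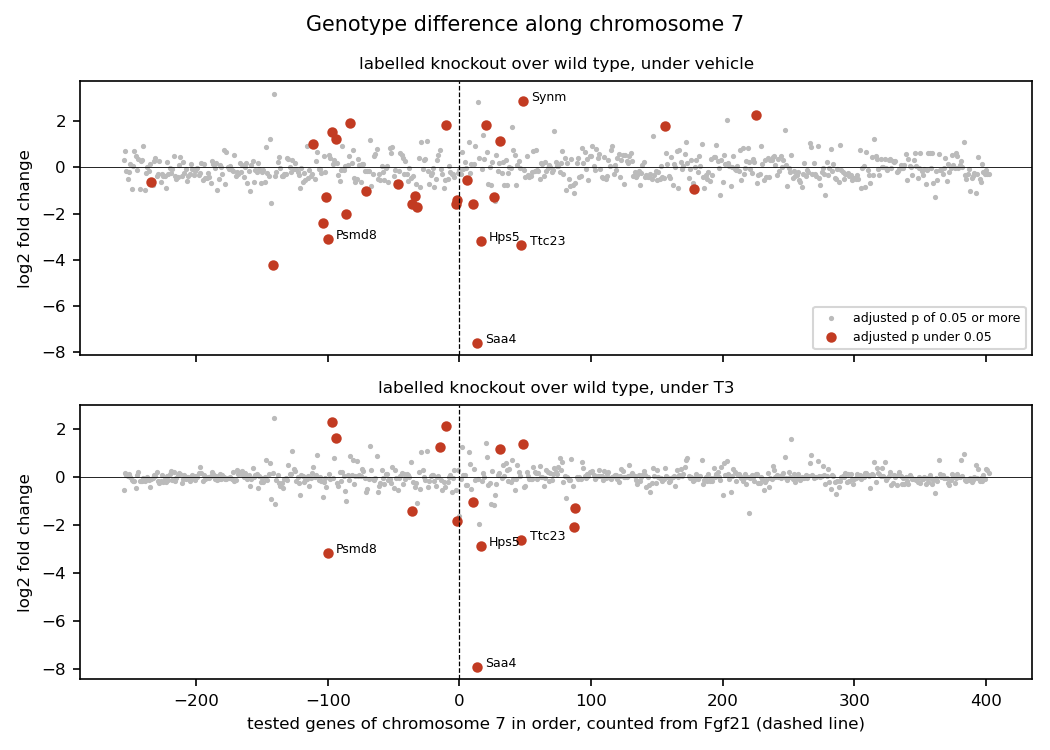
Log2 fold change of arrays labelled knockout over wild type (vertical axes) for the 658 tested genes of chromosome 7 in gene order counted from Fgf21 (horizontal axis), under vehicle and under T3. Points are genes, with those whose adjusted p passed in red. Points are fitted values, also for genes not above background in 1 group. Saa4, 13 tested genes after Fgf21, was at -7.60 under vehicle, where it was above background on 1 of 4 arrays labelled knockout.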

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

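In this part the tests on array brightness and on other splits of the arrays were chosen before their results were seen, and the tests on chromosome 7, probe mismatch, array identity, probe position and hepatocyte share only after the result was seen.

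Probes called the same way in both knockout contrasts concentrated on chromosome 7, which held 64.3% of those with a known chromosome (18 of 28), against 7.41% of tested probes (one-sided Fisher's exact p = 2.5e-14) and 7.51% (p = 0.458) and 8.87% (p = 0.0772) of the T3 calls in wild type and in the arrays labelled knockout. This share is 8.67 times that among tested probes, which argues against a loss of FGF21 that acts without regard to gene position as the source of these calls. The Fisher test counts probes of the same gene and neighbouring genes as independent, so its p overstates the evidence where these vary together. Of the 18 probes 44.4% (8) were higher in the arrays labelled knockout, which argues against a sequence mismatch for these, since a mismatch lowers the signal; for the lower ones another probe was also called lower in 1 of 3 genes (Lgals4, not Lrrc28 or Dhdh), too few to tell a mismatch from lower expression. A candidate explanation is a chromosome segment of another strain carried along with the Fgf21 allele, which would place calls on both sides of the gene, and genes called in both contrasts by their brightest probe lie from position -100 to 48 relative to Fgf21 in the order of tested genes. An effect of the deleted sequence on its neighbours was not tested, and the strain in which the allele was made is not given in the sources used here.

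The Fgf21 probe was above background on 8 of 8 arrays labelled knockout and read 11.80 on knockout T3 replicate 4. On 10 chromosome 7 probes chosen without that array, it lay 0.154 of the way from the knockout to the wild type mean, which argues against a mislabelled genotype. Saa4 read 5.53 on it, against a wild type T3 mean of 13.93 and a floor of 7.16, which argues against RNA of a wild type T3 sample mixed into it. A probe outside the deleted part of the gene may give such signal, but this and other sources of signal cannot be told apart because no positions of the probe or the deletion were used here.

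Macrophage markers were higher in wild type T3 (median log2 fold change 2.19, or 2.06 with 4 members at their bound; 12 of 12 called) and in knockout vehicle (1.79, or 1.27; 7 of 12 called) than in the same 4 wild type vehicle arrays. With array brightness in the model the T3 difference kept 0.996 of its size (2.19, median SE 0.44 before and 0.42 after, 12 still called), which argues against brightness as its cause. The genotype difference kept 0.883 (1.58, median SE 0.44 before and 0.54 after), a share past the bound set beforehand by less than its spread, and all 7 calls ended: 0 of the 7 stayed within the highest unadjusted p called before, so their fold and spread were enough to end them, whereas it was 1.85 with 3 called with the ribosomal mean in the model; the condition that calls be kept and this last check were added after the value was seen, and brightness and genotype cannot be told apart there. Macrophage minus endothelial and stellate means differed by 1.93 and 1.40 (exact permutation p = 0.0286 for each, the smallest that 4 against 4 allows), which argues against a lower share of hepatocytes as the whole cause, since that would raise all 3 kinds of marker alike. More macrophages or more expression per cell, under T3 or in the other genotype, may account for the rest and were not tested.

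Single arrays stood apart from the 3 others of their group in 16 of 280 group values (5.71%), where chance marks about 1 in 20 groups, or 5%. The 95th percentile signal of wild type vehicle replicate 2 was 3248, against 2542 to 2642. The stellate marker mean of knockout vehicle replicate 3 was 9.95, against 9.46 to 9.52. On knockout T3 replicate 4 Sspo read 9.59 (others at least 10.93), Kcnk1 7.16 (8.71 to 8.92) and Hsd17b6 8.35 (6.26 to 6.59). On wild type T3 arrays Pfkfb4 read 10.32 on replicate 1 (others 12.23 to 12.62), Hps5 7.65 on replicate 2 (8.14 to 8.19), Psmd8 12.47 on replicate 3 (12.31 to 12.33) and Ifit2 8.28 on replicate 4 (7.29 to 7.38). On knockout vehicle arrays Hamp2 read 11.12 (13.04 to 13.09) and Atl3 6.35 (9.84 to 10.04) on replicate 2, Saa4 7.40 on replicate 3 (5.20 to 5.44) and Ms4a6d 6.71 on replicate 4 (8.59 to 8.88). On knockout T3 arrays Hps5 read 5.14 (5.19 to 5.20) and Ramac 6.31 (6.90 to 6.94) on replicate 1, and Cyp2b9 8.64 on replicate 2 (5.23 to 5.76). Some of these readings lie in the background. Hps5 and Ramac were above it on 0 of 4 knockout T3 arrays, and Hsd17b6 and Cyp2b9 on 1 of 4. Saa4 was above it on 1 of 4 knockout vehicle arrays, and Atl3 and Ms4a6d on 3 of 4.

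The T3 response of 7 gene lists was lower in the arrays labelled knockout than in wild type by the list test of the interaction: macrophage markers (-1.15), PPAR alpha targets (-0.58), cell cycle (-0.54), gluconeogenesis (-0.50), periportal markers (-0.35), acute phase response (-0.29) and urea cycle and amino acid catabolism (-0.25). For macrophage markers, PPAR alpha targets and cell cycle genes the medians over members that need no bound were -1.15, -0.46 and -0.15. Lower means the signed difference here. Urea cycle and gluconeogenesis genes fell more in the arrays labelled knockout (medians -0.39 and -0.40) than in wild type (-0.14 and -0.07). None of the 7 calls held with an estimated correlation.

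Other splits of the same 8 arrays into 4 and 4 tested whether chance alone gives as many called probes. For T3 in wild type 1 of 35 splits, the real one, gave 1509 (highest other 3). For T3 in the arrays labelled knockout 1 of 35 gave 796 (highest other 1), and for genotype under T3 1 of 35 gave 67 (highest other 1). This argues against chance for these counts but does not exclude it, since 1 of 35 is the smallest share that the splits can give. For genotype under vehicle 2 of 35 gave at least the real 336, and chance is not excluded; the other split, wild type vehicle replicates 1, 2 and 3 with knockout vehicle replicate 3 against the rest, gave 4944, which points to a structure of the samples other than genotype. For the difference of T3 responses 0 probes were found, a count that any regrouping reaches (100 of 100 with the real grouping counted, highest other 5813), so this comparison says nothing about chance. The highest other count points to a structure of the samples. Of the same 100 groupings 18, the real one among them, gave at least the 1146 probes with an unadjusted p under the threshold (highest other 7332, median of the others 376). Chance is not excluded for that number. With array weights 6 of 35 splits gave at least the real 7351 for T3 in wild type (highest other 9343, median 2486.5), so chance is not excluded for that count; the other counts with array weights were not set beside other splits.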

How the results depend on the processing

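The alternatives with array brightness or the ribosomal mean in the model, and without the dimmest and the 2 brightest arrays, were chosen after seeing the data; for each shift below the cause was not tested unless the sentence gives one. With the authors' values, no background correction, an offset of 50, a detection p under 0.05, a fold change minimum of 1.5 and robust eBayes with a trend, the counts of called probes lay at 1352 to 1617 for T3 in wild type (1509 reported), 737 to 871 for T3 in the arrays labelled knockout (796), 0 for the difference of responses (0), 238 to 403 for genotype under vehicle (336) and 58 to 77 for genotype under T3 (67).

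Array weights gave 7351, 4192, 6841, 8625 and 417 in this order. The demand for signal above background on all 16 arrays, which leaves fewer probes, gave 878 for T3 in wild type, 16 for genotype under vehicle and 13 under T3, and left Fgf21 untested. Median scaling gave 473 for T3 in the arrays labelled knockout (174 higher, 299 lower; 419 and 377 reported) and 361 higher and 74 lower for genotype under vehicle (195 and 141 reported), and it moved the median of all probes under T3 in wild type to -0.10. No filter on dim probes gave 134 higher and 217 lower for genotype under vehicle. With only the 8 arrays compared, where fewer arrays estimate the spread, T3 in the arrays labelled knockout gave 389 and genotype under vehicle 20; the difference of responses needs all groups and was not run. Genotype under vehicle gave 33 with brightness in the model. The ribosomal mean gave 2555 and 2706 for T3 in wild type and in the arrays labelled knockout, and 191 and 179 for genotype under vehicle and T3. Without the dimmest and the 2 brightest arrays the difference of responses gave 3 and genotype under vehicle 31.

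Leaving out 1 array gave 912 to 1895 for T3 in wild type, 359 to 1241 for T3 in the arrays labelled knockout, 0 to 3 for the difference of responses, 66 to 3978 for genotype under vehicle and 29 to 95 for genotype under T3. The report names the arrays behind shifts beyond 1.5 times. The highest count for genotype under vehicle came without knockout vehicle replicate 3, and the lowest without replicate 1.

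The Fgf21 rise with T3 in wild type (2.75) kept its direction. Its call was lost with no filter (2.75, adjusted p = 0.111, where more probes are tested) and with brightness (2.64, adjusted p = 0.0514); leaving out 1 array gave 2.25 to 3.18, and the adjusted p over all alternatives ranged from 0.00138 to 0.121. The correlation of the T3 responses of both genotypes (0.564) was 0.1004 with array weights, 0.778 with brightness, 0.787 with the ribosomal mean, 0.786 without the 3 arrays and 0.390 to 0.689 without 1 array. That of T3 and genotype effects (0.603) was 0.725 with array weights, 0.398 with brightness, 0.436 without the 3 arrays and 0.493 to 0.676 without 1 array.

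Replicate numbers do not pair the samples: of 24 pairs of the same number 13 correlated above 0.1 (-0.713 to 0.735), and 3 of 16 arrays were matched best by their own number, where chance gives 4. With the number as a block, genotype under vehicle gave 205 and the Fgf21 call was lost (2.75, adjusted p = 0.0713; range over all alternatives 0.00138 to 0.121). No slide block was run because no array positions were in the sources used here.

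By the direction of the list test 1 called list reversed, urea cycle and amino acid catabolism in the difference of responses, to a median of 0.31 with median scaling (-0.25 reported). The medians of 2 others changed sign without that: tricarboxylic acid cycle under T3 in wild type, to -0.05 with median scaling (0.20 reported), and cell cycle in the difference of responses, to 0.23 with array weights (-0.54 reported). All 36 list calls were lost with an estimated correlation, 12 with array weights and 9 with median scaling, and 0 with the authors' values. None of 168 named gene results reversed; calls were lost for 57 with only the 8 arrays, 50 with no filter, 47 without the 3 arrays, 39 with brightness, 30 with the ribosomal mean, 24 with median scaling and 3 with the authors' values. Genes dimmer than background in 1 group have only a lower bound of their fold.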

Other observations

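The values in this part come from tests planned before the data were examined, except the comparison of each array with the line from vehicle to T3, which was chosen only after the result was seen.

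Elastase genes usually linked to the pancreas rose with T3; they come from a list with too few tested members for a test as a list. Cela1 rose by a log2 fold change of 2.08 (SE 0.35, adjusted p = 0.00186) in wild type and by 2.30 (SE 0.35, adjusted p = 0.00134) in the arrays labelled knockout. Cela2a rose by 2.22 (SE 0.46, adjusted p = 0.00685) in wild type, where it was above background on 2 of 4 vehicle arrays, and was not called in the arrays labelled knockout (1.40, SE 0.46, adjusted p = 0.0885; difference of responses -0.81, adjusted p = 0.578). Stat5a, a transcription factor gene of growth hormone signalling, rose by 1.65 (SE 0.28, adjusted p = 0.00194) in wild type and by 1.40 (SE 0.28, adjusted p = 0.00857) in the arrays labelled knockout. Among periportal hepatocyte markers the cadherin gene Cdh1 rose by 1.10 (SE 0.19, adjusted p = 0.0023) and 1.17 (SE 0.19, adjusted p = 0.00233), and the protease gene Ctsc by 1.51 (SE 0.27, adjusted p = 0.00277) and 1.27 (SE 0.27, adjusted p = 0.0122), in the same order. The periportal list did not pass in either genotype: 2 of 10 were called higher in wild type (median 0.09, camera adjusted p = 0.363; 2 adjusted over the list alone), and 2 higher and 1 lower in the arrays labelled knockout (median -0.24, camera adjusted p = 0.309; 2 and 3 adjusted over the list alone). Hmox1 rose at least 1.52-fold in wild type (adjusted p = 0.000592). The calls of the genes named here held with every array left out in turn.

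Female-biased liver genes split under T3 in wild type, where 3 of 6 rose and 2 fell (3 and 2 adjusted over the list alone), and the list did not pass (median 1.54, or 0.71 with a member not above background at its bound; camera adjusted p = 0.401). Circadian clock genes had a median of -0.58 in wild type (camera adjusted p = 0.0629; adjusted p = 0.434 with an estimated correlation), where the only 1 of 10 called was higher (1 higher and 4 lower adjusted over the list alone), and of -0.03 in the arrays labelled knockout (camera adjusted p = 0.595), and their difference was not called (median 0.27, camera adjusted p = 0.177). Respiratory chain and ATP synthase genes did not pass in wild type (median 0.16, camera adjusted p = 0.0823). Genes that differ between C57BL/6 substrains were not called under vehicle over all probes, where Nnt, the transhydrogenase gene deleted in a common substrain, had a log2 fold change of -1.15 (adjusted p = 0.132) and Wdfy1 of -0.50 (adjusted p = 0.113), while adjusted over the list alone 3 of 3 were lower (median -0.50, camera adjusted p = 0.148). Under T3 none of the 3 was called either way (median -0.04, camera adjusted p = 0.472).

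On the probes called for T3 in both genotypes without the array in question, knockout vehicle replicate 2 lay 0.485 and replicate 1 -0.229 of the way from the vehicle mean to the T3 mean, and knockout T3 replicate 4 lay at 1.04. The macrophage marker mean of knockout vehicle replicate 4 was 8.77, against a group mean of 9.91.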
